A study of Mus musculus with 17 samples.

How the data were processed

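RNA from mouse brain (strain background C57BL/6) was sequenced in 17 libraries, of which 6 came from mice carrying a HAR1A transgene and 11 from normal control mice, per the labels. The labels give neither the part of the brain taken, nor age or sex, nor whether each library came from a separate animal, so p-values measure the spread between these libraries. The transgene libraries were all sequenced on lane 4 of a flow cell that also held 3 controls on that lane, 6 controls on lane 8 and 1 on lane 2. A further control came from lane 6 of another flow cell. Libraries are named by group and by a number given in the order of deposition.

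The authors deposited raw counts per transcript, with 68517 rows for each library. Of these, 64505 rows carried Ensembl transcript names, 4007 carried assembled-locus names (XLOC) and 5 closing rows named no feature. Reads were placed on the mm10 build, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. The closing rows were kept out of library sizes and tests. Reads that fell on several features made up 41.5% ± 0.92 (SD, n = 17) of the total, and reads outside any feature 8.44% ± 1.57. A gene with several overlapping transcripts therefore lost reads that could not be given to a single transcript, and its counts are lower than its true share. The share of such reads was 42.1% ± 0.84 in the transgene libraries (n = 6) and 41.1% ± 0.82 in the controls (n = 11; exact two-sided permutation p = 0.043). Reads outside any feature made up 7.44% ± 1.43 in the transgene libraries and 8.98% ± 1.41 in the controls (exact two-sided permutation p = 0.0496).

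Assigned counts ranged from 17067407 to 22642441 per library. Intervals and floors below cover counting error only. Transcript rows were matched by name without version to GENCODE M21, which is on the same assembly as mm10. The match covered 64380 rows, 62415 of them with the same version, and left 125 unmatched. Counts were summed to 41015 genes. XLOC and unmatched rows were kept as features of their own, giving 45147 features. Of 96 genes named under the rule given below, 53 overlapped another annotated gene. Without a stated strand setting, reads of such neighbours or antisense partners cannot be told apart. Of the same 96 genes, 53 had several deposited rows. Their fold changes rest on reads given to single transcripts and may differ from those of the whole gene.

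Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, the default expression filter, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 values of transgene minus control with standard errors derived from the F statistic. CPM values are scaled with TMM, and log2 CPM used a prior count of 2. The comparisons were transgene against control over all 17 libraries, the same within lane 4 (6 against 3), and lane 8 against lane 4 among controls (6 against 3). A total of 48 gene lists holding 847 entries was fixed, of which 845 were found in the annotation. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01. A list of pituitary genes had 1 tested gene and was left out. The designs, lists, the rule for named genes and most alternative settings were fixed before the data were examined. Under that rule the text names, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 0, predicted genes only if among the 3 largest, up to 4 members of each list that was called or held a called gene, the neighbours of the HAR1 locus, and Reln, Rest, Xist, Ttr, Drd2, Ppp1r1b, Mbp and Fos. Another 5 regional lists were written after the data were examined: Hox genes, brainstem neurons, cerebellar granule cells, Purkinje cells and telencephalic transcription factors.

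No library pair of a group agreed within counting noise: the chi-square statistic per gene was at least 9.97 over 55 control pairs and at least 13.7 over 15 transgene pairs. Where all libraries of a group had 0 counts, the fold is a bound computed against 3 counts over the group (0.0241 CPM in the transgene libraries, 0.0490 CPM in the lane 4 controls). With 1 to 3 counts, the ratio of assigned-count shares is given with its exact 95% interval. The procedure was tested on simulated counts in which 194, 192 and 193 of the tested genes were changed in the 3 comparisons. Over all libraries, 65.6% of genes changed 2-fold and 32.7% of those changed 1.5-fold were recovered among 18677 genes, with 3.06% false calls. Within lane 4, the values were 26.0% and 2.08% among 18795 genes, with 12.9% of 31 calls false. Among controls by lane, they were 28.1% and 1.03% among 18916 genes, with 3.45% of calls false. The simulation changed few genes and drew counts independently for each gene. In the data 47.4% of the tested genes were called over all libraries, so these shares may not carry over. The alternatives covered other scalings and filters, DESeq2 1.42.0, limma-voom, surrogate variables (sva 3.50.0), covariates, other thresholds and leaving out each library. The transgene transcript itself was not analysed here.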

Results

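Brain RNA was compared between mice that overexpress HAR1A and normal mice, to find the genes whose expression goes with this long noncoding RNA in the nervous system. HAR1A is a human noncoding gene that contains a stretch of sequence changed rapidly in the human lineage. Counts were obtained for 6 transgene and 11 control libraries, with 17067407 to 22642441 assigned counts each. The level of HAR1A was not analysed here, so the group labels were not checked against it. The first principal component held 56.7% of the variance over 15704 genes. Control libraries scored between -64.2 and -5.93 on it, and transgene libraries between 56.5 and 88.6.

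**Figure D1:**
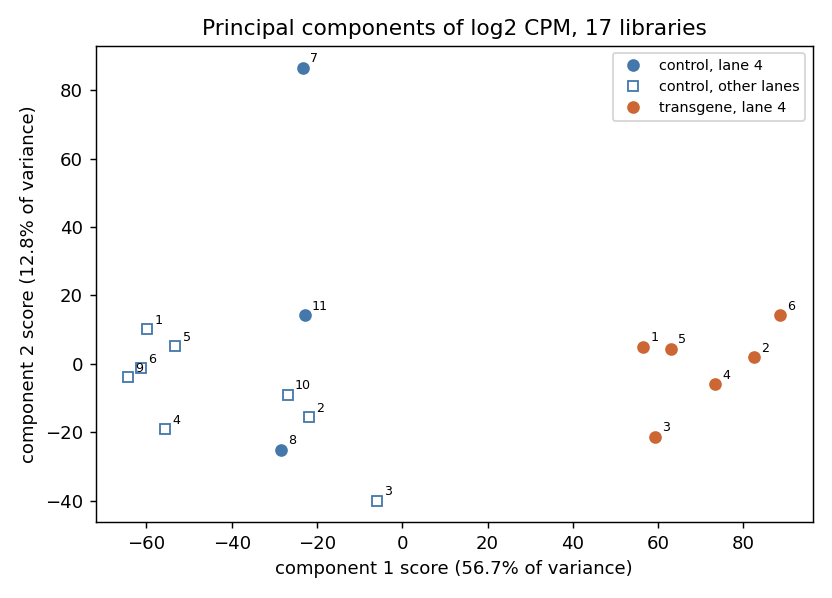
Scores of the 17 libraries on the first and second principal components of log2 CPM, with replicate numbers beside the points. Transgene libraries (orange) lie between 56.5 and 88.6 on the first component and controls (blue, filled on lane 4) between -64.2 and -5.93.

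Genes of striatal projection neurons were higher in the transgene libraries, and Hox genes, which mark hindbrain and spinal cord, were nearly absent from them. The adenosine receptor gene Adora2a (mm10 chromosome 10, 75316877 to 75334784) had 130.1 ± 55.0 CPM (SD, n = 6) in transgene and 5.76 ± 0.97 CPM (n = 11) in control libraries, a log2 fold change of 4.46 ± 0.18 (SE, edgeR adjusted p = 2.06e-11). Lrrc10b rose by 5.34 ± 0.32, Gpr6 by 5.03 ± 0.49, Gng7, a G protein subunit, by 4.79 ± 0.32, the dopamine receptor gene Drd1 by 4.38 ± 0.53 and the interneuron transcription factor gene Dlx6 by 4.37 ± 0.64 on the log2 scale. The other members of the 10 largest rises were Cd4 (5.50 ± 0.31), Gm39043 (5.47 ± 0.53), Dpm3 (4.84 ± 0.69) and the vasopressin gene Avp (5.79 ± 1.02). Dpm3 was at 4.12 log2 CPM in transgene 6, with the next transgene library at 1.60. Avp had 70.6 CPM in transgene 1 and 97.4 CPM in transgene 4 and at most 1.84 CPM in the other transgene libraries. Its adjusted p was 0.0544 with limma-voom, and it ranged from 1.34e-06 to that value over the alternatives other than the regional covariates.

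The 10 largest falls were all Hox genes or their antisense transcripts. Hoxa5 (chromosome 6, 52201754 to 52204587) had 7570 counts in the controls and 3 in the transgene libraries, a ratio of 1439 (95% interval 492 to 6980). Hoxb5 had 9171 counts against 4, a ratio of 1308 (511 to 4800). Hoxa4 had 2289 counts against 1 (ratio 1305, 234 to 51585), Hoxb3 had 1739 against 1 (ratio 992, 178 to 39195) and Hoxc5 had 1538 against 1 (ratio 877, 157 to 34667). The remaining 5 had no count in any transgene library. Hoxa2 was at least 168-fold lower, Hoxd3 at least 139-fold, Hoxb2 at least 117-fold, Hoxa6 at least 103-fold and Hoxb3os at least 95.1-fold. All 21 Hox features past the threshold were lower, with adjusted p for the 10 named between 4.55e-07 and 0.000234. Several overlap one another in the annotation, so their counts are not independent.

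In all, 9078 of 19136 tested genes differed (47.4%, edgeR adjusted p under 0.05), 4410 higher and 4668 lower in the transgene libraries. Of these, 3120 changed at least 2-fold, 1616 higher and 1504 lower. The groups did not overlap in any library for 2824 of the called genes. Genes without overlap were 14.8% of all tested genes, against 0.0162% by chance. With scaling by library size only, 35.6% of the calls were higher instead of 48.6%, and the median log2 fold change of all genes moved from -0.05 to -0.16. With lane and flow cell as a factor, 5887 genes were called. With the mean levels of the granule cell, Hox and telencephalic lists as covariates, an alternative chosen after seeing the data, 0 genes were called by edgeR (1001 at an unadjusted p under 0.05). These 3 scores accounted for 93.3% of the variance of the group term, but the genes of their lists were chosen after their values were seen.

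**Figure D2:**
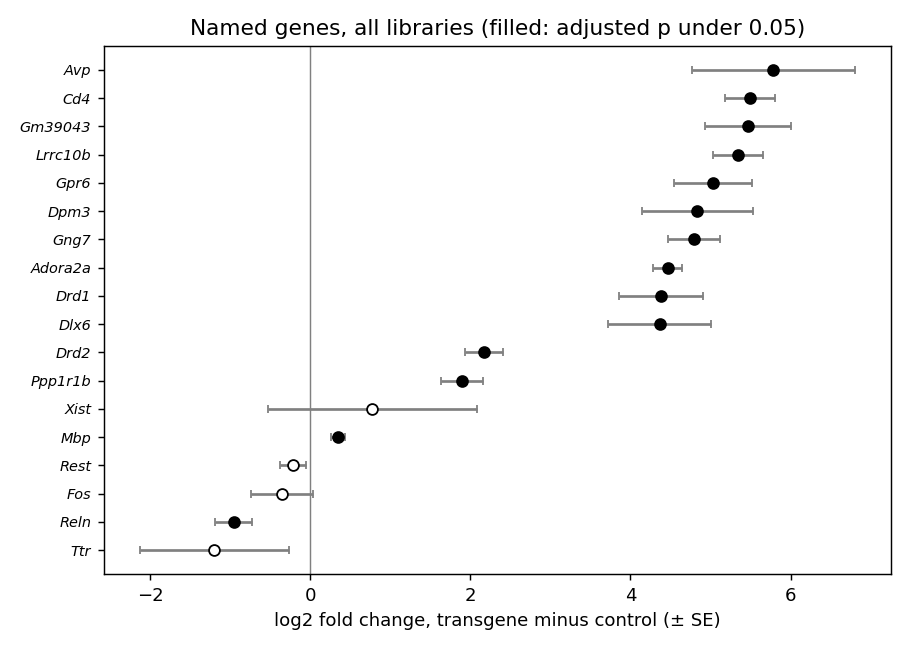
Log2 fold change, transgene minus control, with standard errors over all 17 libraries, for the 10 largest rises and the 8 genes fixed in advance. Filled points passed the adjusted threshold, and Rest, Xist, Ttr and Fos did not.

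The lists written for brain regions after the data were examined moved in opposite directions. All 15 Hox genes of the list were lower, with a median log2 fold change of -8.84, or -7.81 with the 12 members at 0 to 3 counts set at their bounds. All 8 tested brainstem neuron genes were lower (median -4.77), among them the glycine transporter gene Slc6a5 (-7.08 ± 0.70). All 6 granule cell genes were lower (median -4.17), including Gabra6 (-4.71 ± 0.98) and Cbln3 (-4.63 ± 1.19), as were 6 of 7 Purkinje cell genes (median -4.21), including Pcp2 (-4.63 ± 1.07) but not Itpr1 (-0.98 ± 0.40). All 12 telencephalic transcription factor genes were higher (median 3.19), including Emx1 (3.28 ± 0.67) and Tbr1 (3.40 ± 0.85), which act in forebrain and cortical development. Among genes with a single deposited row, which lose no reads to other transcripts of their own gene, all 25 tested members passed in the direction of their list. These genes were chosen after their values were seen.

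**Figure D3:**
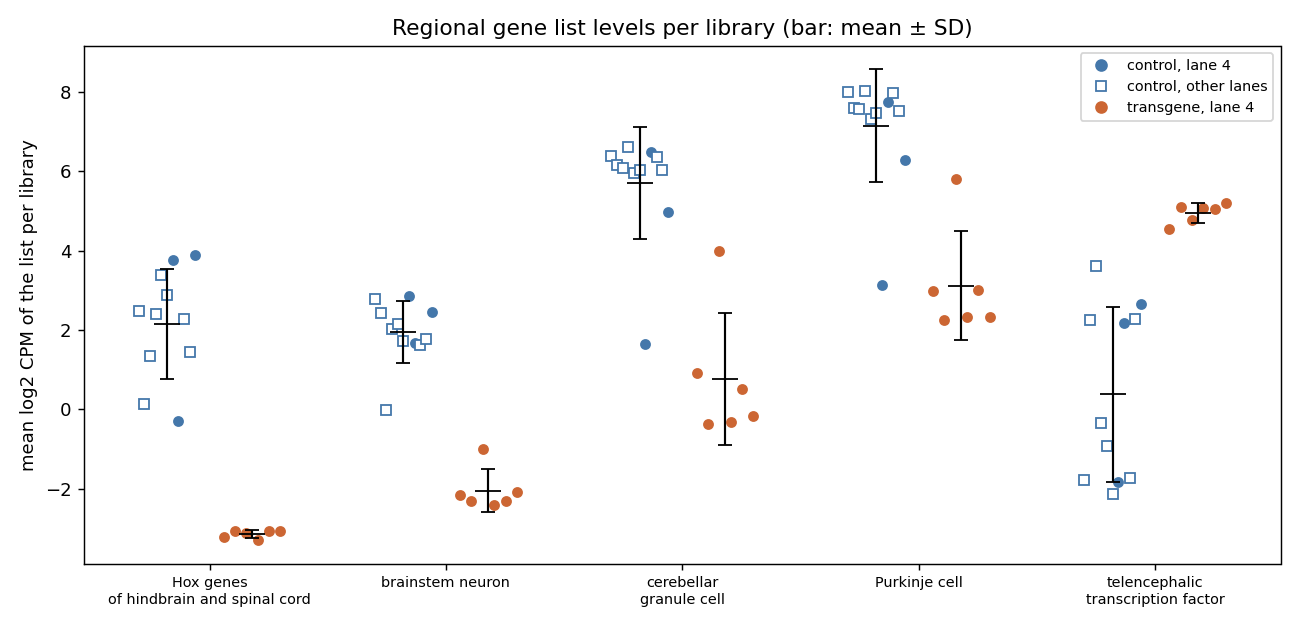
Mean log2 CPM of 5 regional gene lists in each library, with the mean and SD of each group as bars, controls in blue (filled on lane 4) and transgene libraries in orange. The Hox score was between -0.29 and 3.90 in controls and between -3.30 and -3.07 in transgene libraries, and the granule cell score of control 7 was 1.64 and that of transgene 3 was 4.00.

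Among the lists fixed in advance, 18 of 47 were called by camera with the preset correlation, 12 higher and 6 lower. None of the 18 was called with an estimated correlation, where the smallest adjusted p was 0.295. In 6 of 100 splits of the libraries, the real one included, at least as many lists were called, so the number of called lists is within what other groupings gave. The counts of members past the gene threshold are given below with this limit. Of all tested genes, 47.4% were called, so a large count of called members alone does not set a list apart. For the called lists named here, the number of called members was the same adjusted over the list alone, except where stated.

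All 17 genes of striatal medium spiny neurons were higher (camera adjusted p = 1.81e-13, and adjusted p = 0.295 with an estimated correlation). Rasd2 rose by 2.12 ± 0.14, Drd2 by 2.17 ± 0.24 and Ppp1r1b, which encodes the dopamine-regulated phosphoprotein DARPP-32, by 1.89 ± 0.26. Of 16 excitatory neuron genes, 13 were higher and 1 lower (adjusted p = 9.27e-06, and adjusted p = 0.312 with an estimated correlation). The cortical projection neuron genes Bcl11b and Neurod6 rose by 3.12 ± 0.36 and 2.46 ± 0.37. Of 15 inhibitory neuron genes, 10 were higher and 2 lower (adjusted p = 0.00417, and adjusted p = 0.454 with an estimated correlation). The neuropeptide genes Npy, Sst and Cck rose by 2.24 ± 0.27, 1.55 ± 0.19 and 2.22 ± 0.31, while Pvalb, which cerebellar Purkinje cells also express, fell by 2.77 ± 0.28.

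Of 17 cerebellar granule and Purkinje cell genes, 15 were lower and 0 higher (16 lower adjusted over the list alone). The camera adjusted p was 3.5e-05, and the adjusted p = 0.66 with an estimated correlation. Zic1 went from 346.4 ± 127.1 CPM in controls to 49.4 ± 20.5 CPM in transgene libraries, and Cbln1, a synapse organiser of granule cells, from 186.6 ± 72.5 to 14.9 ± 16.3 CPM. Of 14 genes of Cajal-Retzius cells and the reelin pathway, 9 were lower and 1 higher (adjusted p = 0.00571, and adjusted p = 0.295 with an estimated correlation). Lhx1 fell by 4.23 ± 0.68, Lhx5 by 3.29 ± 0.37, Ebf2 by 2.37 ± 0.22 and Calb2 by 1.58 ± 0.16, all of which are also used by neurons outside the cortex. Reln itself had 23.7 ± 3.5 CPM in transgene and 44.8 ± 14.4 CPM in control libraries (log2 fold change -0.96 ± 0.23, adjusted p = 0.00238). With lane and flow cell as a factor its log2 fold change was -0.36 and it was not called.

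Glial lists moved apart. Of 16 astrocyte genes, 9 were lower and 1 higher (adjusted p = 0.00467, and adjusted p = 0.295 with an estimated correlation), with S100b falling by 1.68 ± 0.14, Aqp4 by 1.33 ± 0.13 and Aldoc by 0.93 ± 0.09. Of 17 oligodendrocyte and myelin genes, 12 were lower (13 adjusted over the list alone) and 1 was higher (adjusted p = 0.018, and adjusted p = 0.795 with an estimated correlation). Ermn fell by 1.07 ± 0.27, Trf by 1.02 ± 0.26 and Mobp by 0.80 ± 0.23, while Mbp, a main myelin protein gene, rose by 0.35 ± 0.09 over its 8 deposited transcripts. The Mbp value rests on reads given to single transcripts, so the direction of the whole gene is not shown. Of 13 microglia genes, 9 were higher (10 adjusted over the list alone) and none lower (adjusted p = 0.00571, and adjusted p = 0.66 with an estimated correlation). Tmem119, Laptm5 and Cd68 rose by 0.76 ± 0.14, 0.62 ± 0.13 and 0.84 ± 0.20, and none of these 3, nor Mbp, passed with lane and flow cell as a factor, where their log2 fold changes were 0.41, 0.29, 0.60 and 0.30. The microglia list was not called there either.

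Among receptor, guidance and adhesion genes, more were called higher than lower. The counts were 15 higher and 3 lower of 26 axon guidance genes (Epha4 rose by 1.90 ± 0.21, Efnb2 by 1.24 ± 0.14 and Slit3 by 1.18 ± 0.11), and 14 higher and 2 lower of 24 adhesion and synapse organiser genes (Nlgn1 rose by 0.96 ± 0.11, Lrrtm2 by 0.83 ± 0.10, and Cntn2 fell by 1.02 ± 0.09). Of 22 glutamate receptor genes, 12 were higher and 5 lower, with Grm5 up by 1.95 ± 0.22, Grik5 up by 1.36 ± 0.13 and Gria4 down by 1.12 ± 0.12. Of 21 GABA and glycine receptor genes, 10 were higher and 2 lower. Gabra4 rose by 1.93 ± 0.19 and Gabrb1 by 0.92 ± 0.10, and the glycine receptor gene Glra1, used in brainstem and spinal cord, fell by 4.62 ± 0.60. The median of that list was 0.32 and its mean -0.05. The camera adjusted p of these 4 lists was 0.00308, 0.0087, 0.0372 and 0.0349, and with an estimated correlation the adjusted p was 0.295, 0.332, 0.66 and 0.295. Without control 7 and transgene 3, libraries that stood apart in cerebellar genes, neither receptor list was called, nor were the oligodendrocyte and immediate-early lists. The neural progenitor list was not called with lane and flow cell as a factor.

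Of 20 neuropsychiatric and autism-linked genes, 9 were higher and 1 lower (adjusted p = 0.00308, and adjusted p = 0.295 with an estimated correlation). Shank3 and Foxp1 rose by 2.56 ± 0.24 and 2.16 ± 0.17. Of 20 neural progenitor genes, 11 were higher and 3 lower (adjusted p = 0.0447, and adjusted p = 0.66 with an estimated correlation), with Hes5 up by 1.61 ± 0.19, Stmn1 up by 1.00 ± 0.14 and Vim down by 1.06 ± 0.14. Of 17 transthyretin, thyroid and retinoid genes, 8 were higher and 2 lower (adjusted p = 0.0289, and adjusted p = 0.295 with an estimated correlation), with Rxrg up by 3.37 ± 0.30, Thrb up by 1.51 ± 0.17 and Aldh1a1 down by 2.13 ± 0.19. Of 19 immediate-early genes, 11 were higher (adjusted p = 0.0178, and adjusted p = 0.765 with an estimated correlation). Arc, Junb and Egr1 rose by 1.81 ± 0.36, 1.71 ± 0.31 and 1.70 ± 0.34, while Fos had 62.6 ± 37.6 CPM in transgene and 78.4 ± 35.9 CPM in control libraries (adjusted p = 0.487).

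Of 18 interferon response genes, 11 were lower and 0 higher (adjusted p = 0.00571, and adjusted p = 0.66 with an estimated correlation). Stat2 fell by 1.64 ± 0.32, Ifit3b by 1.14 ± 0.24 and Ifitm3 by 0.45 ± 0.12. Of 23 nuclear oxidative phosphorylation genes, 8 were lower and 0 higher (adjusted p = 0.0085, and adjusted p = 0.765 with an estimated correlation), with Ndufb2 falling by 0.73 ± 0.09 and Uqcrh by 0.39 ± 0.08. The 15 genes encoded in mitochondria were not called as a list (adjusted p = 0.408). Genes of lists that were not called also changed, among them the serotonin synthesis gene Tph2 (-4.47 ± 0.66), Rora (-1.30 ± 0.24), Ebf1 (-2.67 ± 0.16), H2-D1 (-1.14 ± 0.09), Kcnq5 (3.21 ± 0.36), Syn1 (1.05 ± 0.13) and Vgf (1.62 ± 0.23).

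**Figure D4:**
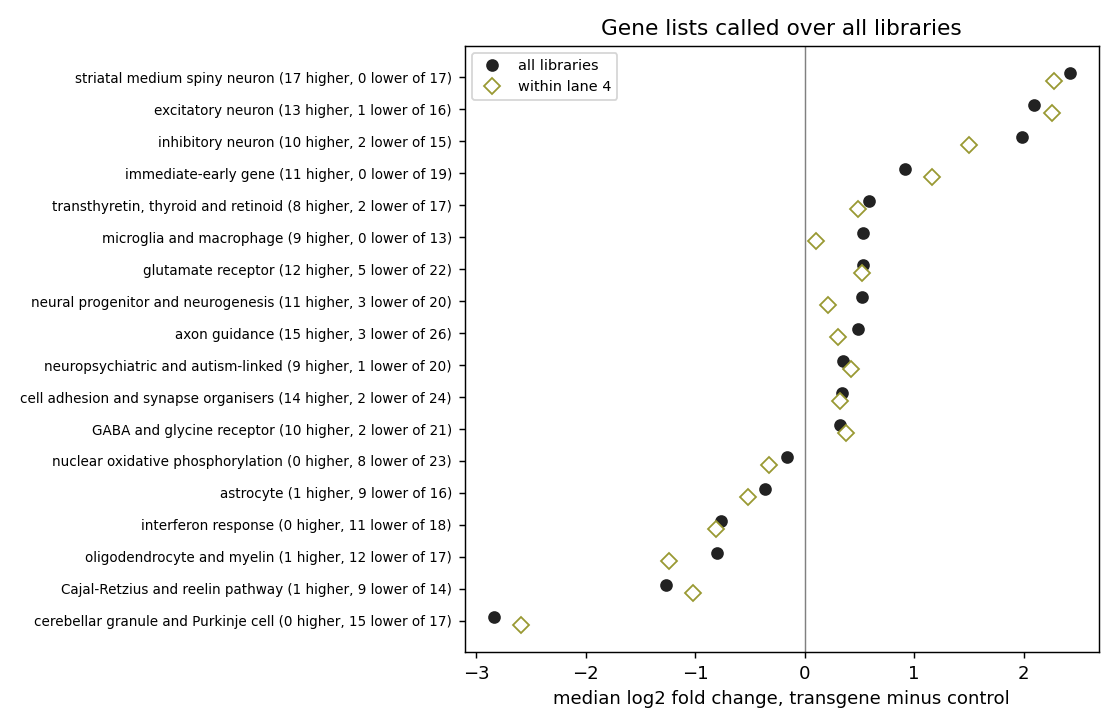
Median log2 fold change, transgene minus control, of the 18 gene lists called by camera with the preset correlation over all libraries (circles), with the value of the same list within lane 4 (diamonds) and the number of members past the gene threshold. None of the 18 was called with an estimated correlation.

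The neighbours of the HAR1 locus on mouse chromosome 2 were not called as a list (adjusted p = 0.489). Of 12 tested, 4 were higher and 2 lower. Ntsr1 rose by 1.44 ± 0.23 and Arfgap1 by 0.69 ± 0.16, and Birc7 fell by 1.43 ± 0.33. Rest, a repressor of neuronal genes, had 1.35 ± 0.17 CPM in transgene and 1.53 ± 0.34 CPM in control libraries (log2 fold change -0.22 ± 0.17, adjusted p = 0.303). Ttr, the choroid plexus transthyretin gene, had 782.1 ± 694.2 CPM in transgene and 1773 ± 1161 CPM in control libraries (adjusted p = 0.307), and Xist 1251 ± 625.5 and 714 ± 701.3 CPM (adjusted p = 0.654).

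Since 8 of the 11 controls were sequenced on other lanes, the comparison was repeated within lane 4, with 6 transgene and 3 control libraries. The 10 largest falls were again Hox genes or their antisense transcripts, and the striatal list genes Lrrc10b, Gng7, Adora2a and Gpr6 were again among the 10 largest rises. Sh3rf2 had 258 counts in the transgene libraries and 0 in the lane 4 controls, at least 44.6-fold higher. Cd4 rose by 5.55 ± 0.46, Lrrc10b by 4.99 ± 0.39, Myl4 by 4.69 ± 0.52, Gng7 by 4.67 ± 0.58, Adora2a by 4.44 ± 0.38, Dsg1c by 4.36 ± 0.79 and Gpr6 by 4.34 ± 0.59. Gm39043 had 307 counts against 1, a ratio of 151.3 (95% interval 27.0 to 5995), and Dpm3 488 counts against 2 (ratio 120.3, 33.1 to 996). Dpm3 stood highest in transgene 6, at 4.12 log2 CPM with the next transgene library at 1.60. With the granule cell score as a covariate, chosen after seeing the data, Dpm3 was not called. Hoxa2 was at least 252-fold lower, Hoxd3 at least 202-fold, Hoxb2 at least 181-fold and Hoxb3os at least 141-fold. Hoxb5 fell by 10.52 ± 1.03 (4 counts in the transgene libraries). Hoxa5 had 3060 counts in the lane 4 controls against 3 (ratio 2070, 708 to 10041), and Hoxa3 had 837 against 3 (ratio 566, 193 to 2751). Hoxa4 had 923 counts against 1 (ratio 1873, 335 to 74050), Hoxb3 had 737 against 1 (ratio 1495, 268 to 59144) and Hoxc5 had 632 against 1 (ratio 1282, 229 to 50729).

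Within lane 4, 4936 of 19261 genes were called, 2617 higher and 2319 lower. Of 18629 genes tested in both comparisons, 4584 were called in both in the same direction and 0 in opposite directions, although the comparisons share 9 libraries and are not independent. At an adjusted p of 0.01, 2451 genes were called within lane 4. The groups did not overlap for 4043 called genes, and genes without overlap were 25.1% of those tested against 2.38% by chance. Of the lists, 21 of 47 were called with the preset correlation, 12 higher and 9 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.288. The striatal list had 15 of 17 genes higher, the excitatory list 13 of 16 higher and the cerebellar list 8 of 17 lower. All 11 tested Hox genes and all 8 brainstem genes were lower, 10 of 12 telencephalic genes were higher, and 4 of 6 granule and 2 of 7 Purkinje cell genes were lower. Control 7, on lane 4, had the lowest granule cell score of the controls (1.64, against a control mean of 5.70), which bears on these cerebellar counts. The microglia list, with 1 of 14 genes higher, was not called (adjusted p = 0.258), nor was the neural progenitor list (0.160). The thalamus and midbrain, endothelial and MHC class I lists were called lower within lane 4, and the circadian clock and Huntington-linked lists higher. Over all libraries these lists had adjusted p of 0.0653, 0.0653, 0.0709, 0.429 and 0.0653, and whether they differ between the comparisons was not tested. The thalamus and midbrain list was not called with the Xist covariate. Without control replicate 7, the circadian clock, Huntington-linked and transthyretin, thyroid and retinoid lists were not called within lane 4.

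To see how far libraries of the same group differ by lane, 6 controls of lane 8 were compared with 3 controls of lane 4. Of 19384 genes, 0 were called by edgeR, with a smallest adjusted p of 0.581, and 1543 had an unadjusted p under 0.05. DESeq2 called 1 gene, Rmi2, named after its value was seen (log2 fold change of lane 8 minus lane 4 1.75, adjusted p = 0.0220). Without control replicate 8, 88 genes were called by edgeR.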

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

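The tests of brain region, lane, transgene effect, cerebellar amount, choroid plexus and microglia were chosen after the results they bear on had been seen. The regression of interferon genes and the other splits of the libraries were set out before their results were seen.

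In 105 groups of 6 transgene values, 8 had an end value far from the others, where about 5.25 are given by chance. In transgene 3 the granule cell score was 4.00 (log2 CPM), with the next library at 0.91, and the Purkinje cell score was 5.82, with the next at 3.01. Xist was 1.27 in transgene 1 and at least 10.3 in the other transgene libraries. Dpm3 was 4.12 in transgene 6, with the next at 1.60, and Ifit3b was 3.86 in transgene 3, with the next at 3.05. Hoxa4 in transgene 6 (-2.65), Hoxb3 in transgene 2 (-2.75) and Hoxc5 in transgene 5 (-2.77) stood apart by a single count, since the other transgene libraries had none.

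Cerebellar, brainstem and Hox genes were lower and telencephalic genes higher in the transgene libraries. The sequencing lane is argued against as the whole cause, since 4936 genes were called within lane 4. Of 34 members of the cerebellar and striatal lists fixed in advance, 32 were called, lower and higher respectively, which restates the pattern and does not separate its causes. Different parts of the brain in the libraries of the groups are a candidate explanation. It cannot be told apart from an effect of the transgene on expression in the same tissue, since the labels do not name the part dissected. The regional scores accounted for 93.28% of the variance of the group term. Their genes were chosen after their values were seen, so this overlap with the groups was partly built in and is not separate evidence. In the covariate fit no gene was called, which that overlap alone could give.

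Ttr and the cerebellar genes differed widely between libraries of the same group. Ttr was 2.83 CPM in transgene 2, 3.49 CPM in transgene 6 and 43.3 CPM in control 3, and between 339.6 and 3785 CPM in the others. Over 17 libraries, deviations of Ttr from the group means went with those of the other choroid plexus markers (Pearson r = 0.951, permutation p = 1e-05, Spearman rho = 0.900, permutation p = 2e-05), and r was 0.946 without transgene 2 and transgene 6. Granule and Purkinje cell scores deviated together (r = 0.9918, rho = 0.978, permutation p = 1e-05 for both, the smallest that 100000 resamples can give), and r was 0.974 without control 7 and transgene 3. These 2 relations, with adjusted p of at most 2e-05, are consistent with choroid plexus and cerebellum being included in some samples and left out of others, while other differences between the animals were not tested.

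Interferon response genes were lower in the transgene libraries, by 0.64 ± 0.19 log2 units (SE) in the mean of 18 genes, a difference of -0.64 (95% interval -1.05 to -0.22). A lower share of microglia is argued against, since the median log2 fold change of the microglia list was 0.5358. Within lane 4 that median was 0.10 with none of 14 genes called lower, while the interferon list was at -0.81, so the rise of microglia genes is not shown apart from the lane. With the 3 regional scores as covariates the difference was 0.5563 ± 0.65 (-0.86 to 1.97). That interval holds both 0 and the first value because the scores overlap the groups, so brain region as the cause cannot be told apart from other differences between the groups.

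For the gene counts of transgene against control, no other split that was tried gave as many. The smallest share that these splits can give is 1 of 100 and 1 of 84. Since the groups already stood apart on the first principal component, the splits restate that separation and do not show its cause. Over all libraries, 1 of 100 splits, the real one, gave as many genes (9078, highest other 5192). That other split kept 5 of the 6 transgene libraries together. Within lane 4 it was 1 of 84 splits (4936, highest other 63). For the number of lists within lane 4, 2 of 84 splits gave as many (21, highest other 21). That share is under 0.05, but another split called the same number, so the count does not stand above what other groupings gave. For the lists over all libraries, 6 of 100 splits gave as many (18, highest other 23), so chance is not excluded. Between lanes among controls, all 84 splits called at least the 0 genes of the real one, as any split must, so this count tests nothing (highest other 7).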

How the results depend on the processing

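The fits with regional or granule cell scores, those without control 7 and transgene 3 and those of single deposited rows were chosen after seeing the data. Over all libraries, the count of called genes stayed within 1.5 times of 9078 except with lane and flow cell as a factor (5887) and with 3 regional scores as covariates (0), which overlap the group term. Without each library in turn it ranged from 8177 (without transgene replicate 2) to 9550 (without control replicate 7). It was 9113 without control 7 and transgene 3, 8323 of them among the main calls. Within lane 4 it was 2451 at an adjusted p of 0.01 and ranged from 3712 to 4863 without each library in turn. Between lanes among controls, the count was 1 with DESeq2 and from 0 to 88 without each lane 4 control in turn. The cause was not tested. With an estimated correlation, 0 lists were called over all libraries and 0 within lane 4. Without control 7 and transgene 3, 14 of the 18 lists kept their call, and the oligodendrocyte, glutamate receptor, GABA and glycine receptor and immediate-early lists lost it. Over all libraries, fry did not call the oligodendrocyte list, and camera on ranks did not call the neural progenitor, glutamate receptor and GABA and glycine receptor lists. Within lane 4, fry did not call the cerebellar, oligodendrocyte, immediate-early and circadian clock lists, camera on ranks did not call the axon guidance, glutamate receptor, GABA and glycine receptor and circadian clock lists, and the thalamus and midbrain list was not called with the Xist covariate.

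Deviations of 9 pairs of libraries with the same first number in their titles correlated from -0.40 to 0.35, and 5 of 9 were above 0.1. Without values for pairs of different numbers, these do not decide whether the first number pairs the libraries. With this number as a replicate block, 7503 genes were called over all libraries and 3041 within lane 4. Of the 18 lists over all libraries, 16 kept their call, and the neural progenitor and glutamate receptor lists lost it. Within lane 4, 19 of the 21 did, and the GABA and glycine receptor and the transthyretin, thyroid and retinoid lists lost it. Apart from the genes fixed in advance, named genes were picked for large fold changes or small p in the main fit. The alternatives reuse the same libraries, so agreement was favoured from the start and the fits are not separate checks. Named genes kept their direction and their side of the threshold in 3116 fits over all libraries and 417 within lane 4. A call was lost without a change of sign in 85 and 1, the latter for Dpm3 with the granule cell score. Of the 85, 79 were with the regional scores, where log2 fold changes moved by different amounts: Adora2a was at 4.20, Cd4 at 4.78 and Gm39043 at 4.93, but Gng7 at 2.88, Drd1 at 1.23, Gpr6 at 0.56, Dpm3 at 0.45 and Hoxa5 at -3.60. The log2 fold change changed sign in a further 14 fits over all libraries. All genes of these fits except Rest, Xist, Ttr and Fos, which were not called to begin with, lost their call too. With the Xist covariate, Xist was at -0.036. With the regional scores, Avp was at -0.50, Dlx6 at -0.20, Rest at 0.11, Xist at -5.83, Ttr at 1.92, Fos at 0.22, Birc7 at 0.023, Tle4 at -0.045, Trf at 0.20, Tmem119 at -0.045, Cd68 at -0.14, Egr1 at -0.026 and Ifit3b at 0.25, all with adjusted p of 1. Within lane 4, 3 controls limit what can be called: the simulation recovered 26.0% of genes changed 2-fold.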

Other observations

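Control 7 held transcripts of pituitary hormones: Gh was 966.6 CPM, Pomc 88.2 CPM and Cga 21.8 CPM there, and at most 1.09, 0.27 and 0.15 CPM in the other 16 libraries. The same library had 16.0 CPM of Cbln3 against 381.4 to 1243 CPM in the other controls. Oxt, the oxytocin gene, followed Avp, with 33.7 CPM in transgene 1 and 14.2 CPM in transgene 4 and at most 1.56 CPM elsewhere. The neutrophil granule gene Ngp was 94.9 CPM in control 3, 52.9, 54.0 and 111.5 CPM in transgene 2, 4 and 6, and at most 14.8 CPM in the others. The Y-linked gene Ddx3y was between 113.8 and 142.2 CPM in controls 3, 4, 5, 8 and 11 and in transgene 1, and at most 0.24 CPM in the others. Xist, named in advance, was at most 3.87 CPM in the libraries with Ddx3y and at least 899 CPM in the others. Read as sex, these 2 genes give a different mix in the 2 groups. With Xist as a covariate, 8508 genes were called over all libraries and 3388 within lane 4. Apart from Xist, the genes of this paragraph were chosen after their values were seen.

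In the mouse interval on chromosome 2 between Bhlhe23 (mm10, from 180774381) and Ythdf1 (to 180920949), which was looked at after the data were seen, noncoding genes moved in both directions. Gm14340 had a log2 fold change of 1.29 ± 0.35 (edgeR adjusted p = 0.00504) and, within lane 4, of 1.57 (adjusted p = 0.0867). Gm14344 was at -2.05 ± 0.54 (0.00412) and Gm14339 at -2.29 ± 0.70 (0.0115), both below 1 CPM on average and not tested within lane 4. Gm14344 and Gm14339 overlap on the same strand, so their falls may not be independent. Of all tested genes, 47.4% were called, so calls in this interval do not set it apart. The most abundant, Gm27032, had 31.9 ± 5.5 CPM in transgene and 26.3 ± 7.4 CPM in control libraries (0.313), and Ythdf1 25.8 ± 1.8 and 28.5 ± 3.5 CPM (0.0689).

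XLOC features took 0.372% ± 0.040 of assigned counts in the transgene libraries (n = 6) and 0.466% ± 0.045 in the controls (n = 11; exact two-sided permutation p = 0.000646). Over all libraries, 709 of them were among the called features. Of XLOC and unmatched features together, 46.8% of those tested were called, close to the 47.4% of all tested features.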
